A study of Mus musculus with 4 samples.

How the data were processed

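The series holds 4 RNA sequencing libraries of mouse splenic MHC class II positive cells, 1 from day 0 (unstimulated) and 3 from day 1 (24 h with 50 µg/ml PSA). Per the labels' protocols, RNA was isolated with Qiagen RNeasy kits and libraries were sequenced on an Illumina HiSeq, the 3' adaptor was removed, and reads shorter than 10 nt were left out. Per the submitters' processing notes, cutadapt, TopHat 1.4.1, Cufflinks 2.2.1 and Cuffdiff were used, with genome build GRCm38.p6. The annotation release, strand handling and treatment of reads that fit several places are not given in the sources used here. With reads as short as 10 nt allowed, a read can fit several genes, so values of pseudogenes, microRNA genes and members of gene families are uncertain.

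One table of 17519 genes was used. It gives the FPKM of each library, which the authors made with Cufflinks per the labels' protocols. It also gives the authors' log2 fold change of day 1 over day 0, a mean log2 abundance (logCPM), a p-value and a false discovery rate, per the file headers. The labels name Cuffdiff with a q-value of 0.05 as the authors' test, but the headers of these deposited columns do not name a test, so the scaling and spread estimate behind the authors' p-values and folds are not known. They are cited only as the authors' deposited table, and a call there means a false discovery rate under 0.05.

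Depth was estimated from the FPKM values, since no read counts were used here. For 1221 single-transcript protein-coding genes of at least 1 kb in GENCODE M21 (GRCm38, which holds 16232 of the 17519 gene IDs), the FPKM times the length in kb was searched for the step that 1 fragment is worth. The step was 4.58 at day 0 and 0.328, 0.291 and 0.211 at day 1. Of the low values, 64.3% at day 0 and 68.0%, 69.6% and 71.9% at day 1 lay within 0.1 of a whole number of fragments, where chance gives 20%. The day 1 libraries were 14.0, 15.7 and 21.7 times as deep as the day 0 library. A floor of 3 fragments in a 2 kb transcript is an FPKM of 6.87 at day 0 and of 0.492, 0.437 and 0.317 at day 1, for counting error only. A 0 at day 0 can be a failed estimate, since genes that every cell uses, such as Rps27, are also at 0, so such genes are described as listed at 0, with each library's value and no fold. On simulated values the step was recovered within 0.242%. Estimated fragments of any gene use the length of all its annotated exons together, which can overstate them for genes with several transcripts.

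Changes were tested with limma 3.58.1 (trend, in R 4.3.3) on log2(FPKM + 1), for the 13903 genes with an FPKM of at least 1 in a library, with Benjamini-Hochberg adjustment and a threshold of 0.05. The lone day 0 library was assumed to vary like the 3 day 1 libraries, which leaves 2 residual degrees of freedom (prior degrees of freedom 1.27), and its greater counting error is not in the standard errors. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes, while a fold is the ratio of FPKM means. On simulated data for this comparison, with 50 changed genes per size among 13903, the test recovered 6%, 56%, 94% and 98% of changes of 1, 2, 3 and 4 on the log2 scale and called 1 unchanged gene. Every simulated library, day 0 included, had the mean and spread of day 1, and the changed genes were drawn from the more highly expressed ones. The shallow depth and the zeros of day 0 were not simulated, so these rates do not measure false calls in the real data. No gene had the same value above 0 in all 3 day 1 libraries.

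The 26 gene lists, the named genes and the alternatives were fixed before the data were examined, except where said otherwise. A list is described by how many members passed the test, by the median log2 change of all measured members, and by the percentile of that median among 10000 random lists of the same size matched on deciles of mean expression, which describes these libraries and is not a test across replicates. On simulated data a list of 15 genes shifted by 2 lay at percentile 100, and 4% of 200 unshifted lists lay outside the central 95%. The lists were also tested with limma's camera at a preset correlation of 0.01 and with an estimated one, adjusted over the lists. With the estimated correlation no list passed, and none had an unadjusted p under 0.05. Of 423 list entries, 408 were measured, after symbols were matched through gene IDs. Counts adjusted over the list alone are the same as over all genes where only 1 count is given.

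Named genes were the 10 largest rises and the 10 largest falls among genes past the threshold with an FPKM of at least 10 in the higher group and the same direction in all 3 day 1 libraries, up to 4 members per list with the largest change, and 19 genes fixed by name, of which 18 were in the table and Nos2 was not analysed here. Immunoglobulin and T cell receptor gene segments were not named under the first part. Single members of a list named beyond the largest 4 were chosen after their values were seen. A further rule, 12 genes per direction that both tests called, protein-coding and above 0 in all 4 libraries, ranked by the authors' false discovery rate, was also added after the values were seen.

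Alternatives were a pseudocount of 0.1 or 5, no filter on low values or a higher one, a threshold of 0.01, a change of at least 2-fold, libraries scaled to an equal upper quartile or to a median log2 ratio of 0, the mean of a list's members, leaving out each day 1 replicate, and the authors' calls. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Coordinates are those of GENCODE M21 on GRCm38.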

Results

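RNA was sequenced from mouse (C57Bl.6) spleen cells carrying MHC class II, which were isolated with magnetic beads. One library came from freshly isolated, unstimulated cells (day 0), and 3 libraries came from cells kept for 24 h with 50 µg/ml polysaccharide A (PSA), a sugar polymer of the capsule of the gut bacterium Bacteroides fragilis (day 1). The series asks how antigen presenting cells respond to PSA and whether macrophages with an anti-inflammatory profile arise. Expression was deposited as FPKM for 17519 genes in each library. No library of cells cultured for 24 h without PSA was analysed here, so each difference below combines PSA with a day in culture and with any difference in how the lone day 0 library was prepared. Nothing in the labels says whether the 3 day 1 libraries came from separate mice or cultures, so the p-values measure the spread between these libraries, which may be technical.

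The day 0 library was much shallower than the others. The lowest FPKM values fell on steps that correspond to whole fragments, and these steps made the day 1 libraries 14.0, 15.7 and 21.7 times as deep as the day 0 library. A 2 kb transcript with 1 fragment has an FPKM of 2.29 at day 0 and of 0.164, 0.146 and 0.106 at day 1. At day 0, 7378 genes were listed at 0, against 2663, 2531 and 2073 in the day 1 libraries. Protein-coding genes held 11.5% of the summed FPKM at day 0 and 80.2%, 82.2% and 83.4% at day 1, while small and ribosomal RNA genes held 51.8% at day 0 and 5.58%, 3.71% and 3.52% at day 1. These are not shares of fragments, because FPKM is scaled by gene length and short genes weigh more in the sum. At day 0, AL807811.1, of 60 nt, had an FPKM of 43435 for about 569 fragments, and Actb one of 3296 for about 1928. Across the 13903 genes with an FPKM of at least 1 in a library, which are not independent replicates, the correlation of log2(FPKM + 1) was 0.938, 0.933 and 0.951 between pairs of day 1 libraries and 0.608, 0.582 and 0.579 between day 0 and each of them.

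**Figure D1:**
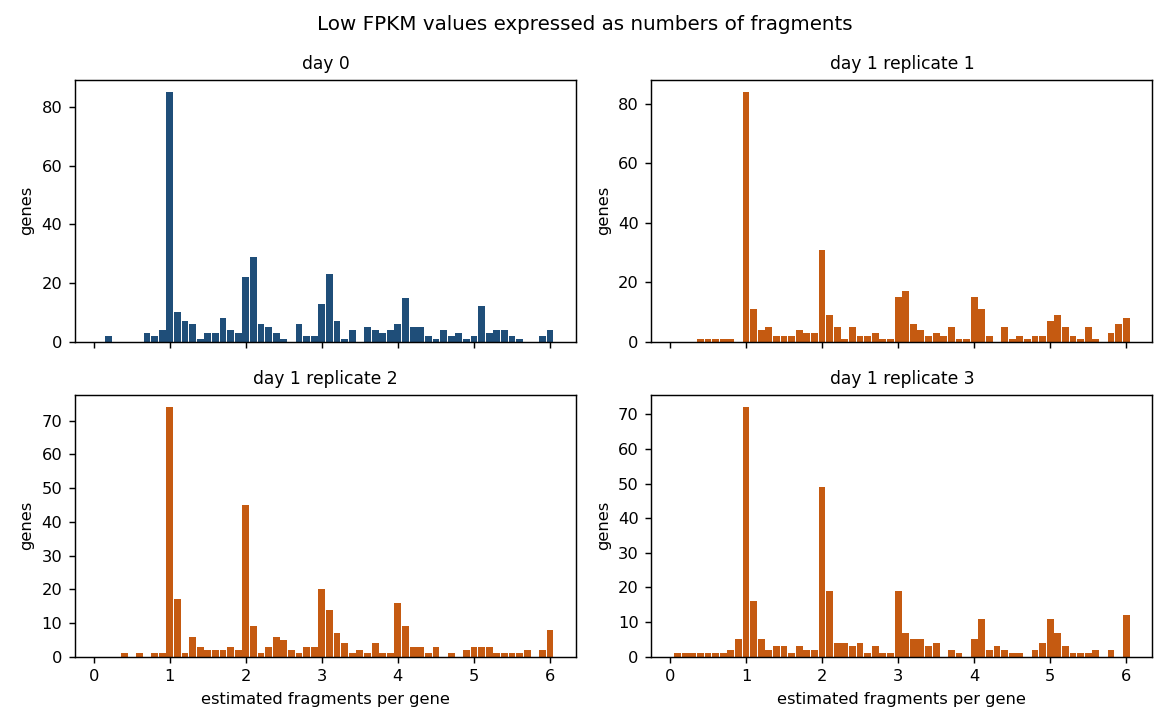
Low FPKM values of single-transcript protein-coding genes, converted to numbers of fragments (x axis) and counted in bins of 0.1 (y axis, genes), for the day 0 library and each day 1 library. Values gather at whole numbers in all 4 libraries, and 64.3% of the values tested at day 0 lay within 0.1 of a whole number, where chance gives 20%.

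Freshly isolated cells carried early stress and activation transcripts, several of which, such as Fos and Fosb, were far lower after 24 h with PSA. Some transcripts of macrophages and dendritic cells were lower too, while others of the same cells were not. After 24 h, Id3, Apoe, Ccl22, Clcf1 and other genes were higher. With limma, 4869 of 13903 genes rose and 2640 fell (adjusted p under 0.05), and 2079 of the rises were of genes listed at 0 at day 0. The median log2 change of all tested genes was 0.59, but 0.018 over the genes above 0 at day 0. The balance of rises and falls depended on this: with the median set to 0, limma called 3360 rises and 3869 falls, and without the genes listed at 0 it called 2834 and 2719. A gene at 0 at day 0 can only rise, so leaving such genes out lowers the median and the count of rises by its construction. The authors' deposited table calls 492 genes at a false discovery rate under 0.05, of which 49 rose and 443 fell. Both tests called 48 rises and 418 falls in the same direction, and no gene was called in opposite directions. Of the 48 shared rises, 30 were of genes listed at 0 at day 0. Of the 418 shared falls, 292 were of protein-coding genes. Leaving out day 1 replicate 2 lowered limma's count from 7509 to 3634 genes, and the lone day 0 library was assumed to vary like the day 1 libraries.

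Immediate early and heat shock genes, which cells switch on within minutes of stress or stimulation, fell as a group. Of 21 measured members, 16 fell and 4 rose in limma, with the same counts adjusted over the list alone, and the authors' deposited table calls 12 of them lower and none higher. Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477273, GRCm38), had an FPKM of 260 at day 0 and 1.15 ± 0.23 (SD, n = 3) at day 1, a 226-fold difference, with a log2 change of -6.93 ± 0.19 (SE, limma adjusted p = 0.0029). Fosb went from 74.4 to 0.556 ± 0.226 (SD, n = 3), Jun from 98.0 to 4.74 ± 0.59 (SD, n = 3), and Klf4, a transcription factor, from 28.3 to 0.561 ± 0.300 (SD, n = 3). Dusp1, a phosphatase that restrains MAP kinases, was 19.1-fold lower, at 6.09 ± 1.17 (SD, n = 3) against 116. Hsp90aa1, a chaperone, went from 2547 to 101 ± 14.7 (SD, n = 3), a log2 change of -4.65 against -2.50 in the authors' deposited table. Hspa8, Dnajb1, Btg2 and Ier3 rose in limma, of which Ier3 was listed at 0 at day 0 and at 3.60, 2.12 and 2.31 at day 1. In the authors' deposited table none of these is called, and Hspa8 and Dnajb1 have log2 fold changes of -0.15 and -0.71. The list's median log2 change of -1.51 lay below all 10000 random lists matched on expression. Camera put the list below the other genes with the preset correlation (adjusted p = 4.2e-05) but not with an estimated one (adjusted p = 0.78).

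**Figure D2:**
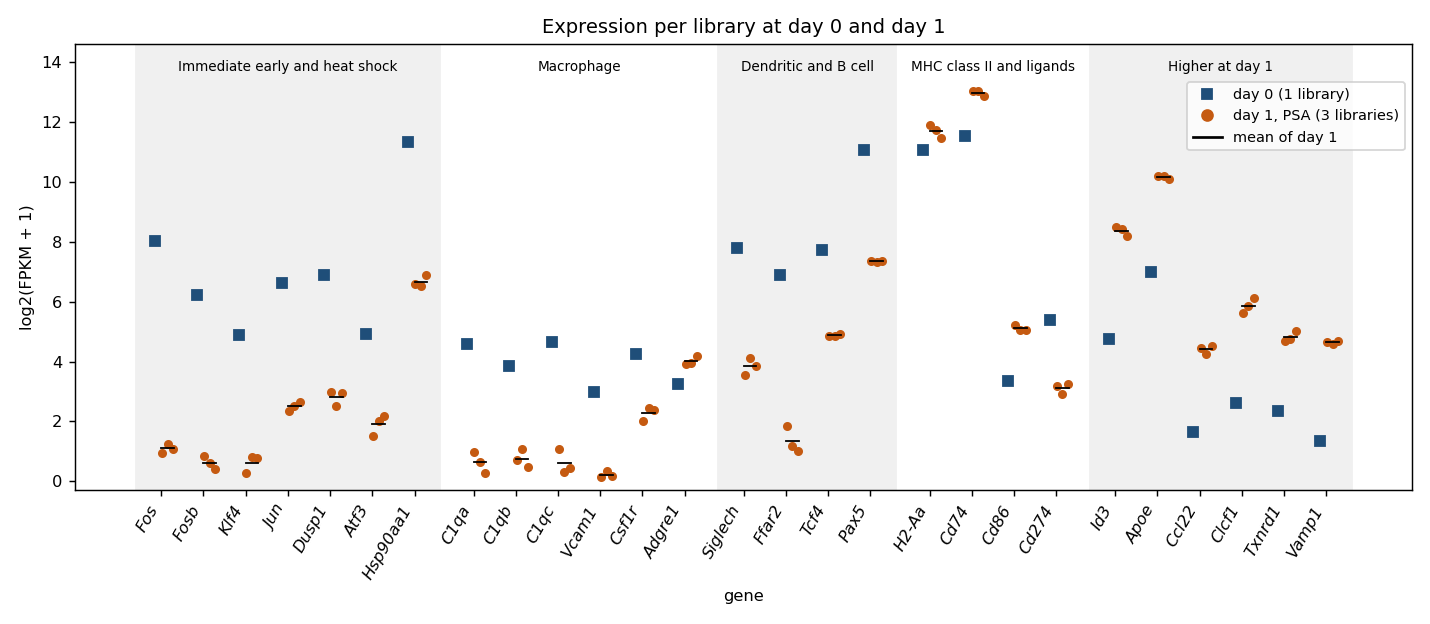
Expression of 27 named genes as log2(FPKM + 1) (y axis) in the day 0 library (blue squares) and the 3 day 1 libraries (orange circles, with their mean as a black line). Fos, Jun and the other immediate early genes shown lie far below their day 0 level in all 3 day 1 libraries, as do C1qa, C1qb and C1qc, while Adgre1 lies slightly above its own and Id3 and Apoe lie well above theirs.

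Part of the macrophage and monocyte markers fell. Of 17 tested members, 9 fell (among them Csf1r, Ccr2, Vcam1, C1qa, C1qb, C1qc, Marco and Cd5l) and 3 rose (Adgre1, Cd68 and Lyz2) in limma, or 9 and 4 adjusted over the list alone. The 3 chains of complement C1q, made by resident macrophages and encoded side by side on chromosome 4 (136880129 to 136898803, GRCm38), went from FPKMs of 23.2, 13.3 and 23.9 to 0.589 ± 0.387, 0.713 ± 0.362 and 0.579 ± 0.478 (SD, n = 3) for C1qa, C1qb and C1qc. These are 39.3-fold, 18.6-fold and 41.2-fold differences, and the authors' deposited table also calls all 3 lower, with log2 fold changes of -5.80, -5.21 and -5.72. The day 0 values of C1qa, C1qb and C1qc stand for about 5.3, 3.2 and 10.1 fragments. Vcam1, an adhesion molecule, went from 6.87 to 0.158 ± 0.087 (SD, n = 3), and Csf1r, the receptor for macrophage colony-stimulating factor, from 18.2 to 3.89 ± 0.74 (SD, n = 3). Adgre1, which encodes F4/80, rose from 8.61 to 15.2 ± 1.7 (SD, n = 3; limma adjusted p = 0.038), a call that ended when the median change was set to 0 and when any 1 day 1 library was left out. The list's median of -0.55 lay at percentile 0.49 of the random lists, and its camera adjusted p was 0.097. Over the members above 0 at day 0 the median was -1.45, at percentile 3.08, which is inside the central 95%. In the authors' deposited table, 8 members are called lower and none higher, and the median of -2.02 lay below all 10000 random lists. The 3 limma rises are not called in the authors' deposited table, where Adgre1 stands at 1.23, Cd68 at 0.33 and Lyz2 at -0.44.

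Dendritic cell markers fell in 7 and rose in 3 of 15 tested members (7 and 4 adjusted over the list alone). Siglech, a surface receptor of plasmacytoid dendritic cells, went from 222 to 13.5 ± 2.7 (SD, n = 3), Ffar2, a receptor for short-chain fatty acids, from 119 to 1.63 ± 0.86 (SD, n = 3), and Xcr1, a chemokine receptor of cross-presenting dendritic cells, from 3.84 to 0.0933 ± 0.1063 (SD, n = 3). Flt3, Ccr7 and Dpp4 rose. The list's median of -0.43 lay at percentile 1.84, at percentile 2.74 without day 1 replicate 3, and at percentile 9.06 (median -0.69) over the members above 0 at day 0. On the log2 fold changes of the authors' deposited table it was -0.54 (percentile 0.36), with 4 members called lower and none higher. B cell markers rose in 10 and fell in 3 of 17 members, with a median of 1.13 (percentile 95.9). Pax5, the transcription factor that maintains B cell identity, fell from 2118 to 161 ± 3.3 (SD, n = 3) and is called lower in the authors' deposited table, as is Cr2. The authors' deposited table calls no B cell marker higher. Plasma cell genes rose in 5 of 8 members and none fell (percentile 94.0), and 2 of the 5 rises were of genes listed at 0 at day 0. The authors' deposited table calls no plasma cell gene, and the list's median there was 0.09 (percentile 62.4). T and NK cell markers rose in 4 and fell in 3 of 15 members (percentile 24.2), among them Klrb1c at 16.1 against 1.25 ± 0.26 (SD, n = 3). On the log2 fold changes of the authors' deposited table this list's median was -0.49 (percentile 0.33), with 2 members called lower and none higher. Neutrophil markers rose in 6 of 10 members, and all 6 were listed at 0 at day 0 (percentile 91.7). Of the erythroid markers 1 of 7 fell and none rose (percentile 43.6), of the platelet and megakaryocyte markers 1 of 3 rose and 1 fell (percentile 69.0), and neither of the 2 tested stromal and endothelial markers changed (percentile 5.13).

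Genes associated with M2 macrophages, the state usually called anti-inflammatory, showed no change as a group, with 5 of 12 tested members rising and 3 falling and a median of 0.41 (percentile 89.2, camera adjusted p = 0.65). Ccl22, a chemokine that attracts regulatory T cells, rose 9.62-fold, from 2.10 to 20.2 ± 2.1 (SD, n = 3; log2 change 2.77 ± 0.17, SE, limma adjusted p = 0.0041), and is the only list member that the authors' deposited table calls higher. Fn1, a matrix protein, fell from 1.79 to a mean of 0.017 and is called lower in the authors' deposited table, where the list's median was -0.41 (percentile 11.8). At day 0 the value of Ccl22 stands for about 1.07 fragments. Il10, an anti-inflammatory cytokine, was listed at 0 at day 0 and at 2.58, 4.56 and 3.47 at day 1; limma called a rise, but the log2 fold change in the authors' deposited table was -0.33 (false discovery rate 1). Arg1 was listed at 0, 0.455, 0 and 0 in day 0 and the day 1 libraries, Mrc1 at 0, 0.246, 0.269 and 0.116, and Cd163 at 0, 0, 0.071 and 0.046. In the authors' deposited table, Mrc1 and Cd163 have log2 fold changes of -2.86 and -3.40 without a call, so the 0 at day 0 does not show absence. M1-associated genes, linked to inflammation, rose in 7 and fell in 1 of 12 tested members (median 0.78, percentile 95.2, camera adjusted p = 0.18). Of these, Tnf was listed at 0 at day 0 and at 2.86, 3.44 and 6.20 at day 1, Il1b at 0 and then 2.49, 3.52 and 3.19, and Il12a at 0 and then 5.84, 7.29 and 6.14. Tnf, Il1b and Il12a have log2 fold changes of 0.73, -1.32 and -0.30 in the authors' deposited table, where the list's median was 0.16 (percentile 75.8). Il6 was listed at 0 at day 0 and at 0.628, 0.276 and 0.603 at day 1. Its day 1 level predicts about 0.27 fragments at day 0, so that 0 does not show whether Il6 changed. The log2 fold change of Il6 in the authors' deposited table, 3.99, is not called. Il12b, with a log2 change of 0.71, did not pass the limma test. The authors' deposited table calls no M1-associated gene. Among chemokines, 3 of 9 rose and 1 fell (percentile 90.1). Toll-like receptors and adaptors rose in 10 and fell in 4 of 19 members, or 12 and 4 adjusted over the list alone (percentile 88.8), and 7 of the 10 rises were of genes listed at 0 at day 0. Tlr2, which recognises bacterial lipoproteins, was listed at 0 at day 0 and at 3.18, 3.78 and 4.43 at day 1. The day 1 level of Tlr2 predicts about 2.5 fragments at day 0. Its log2 fold change of 0.26 in the authors' deposited table is not called. On the log2 fold changes of that table, which calls no Toll-like receptor or adaptor, the list's median was -0.012 (percentile 40.5).

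Antigen presentation genes changed little relative to other genes. MHC class II genes rose in 7 and fell in 1 of 13 members, with a median of 0.91 (percentile 83.0), and the median log2 fold change in the authors' deposited table was -0.10. Cd74, the invariant chain, went from 2936 to 8056 ± 524 (SD, n = 3), a call that ended in the same ways as that of Adgre1, and H2-Aa from 2130 to 3341 ± 508 (SD, n = 3), which did not pass the test (limma adjusted p = 0.12). MHC class I genes rose in 4 and fell in 2 of 13 members (percentile 19.4). Costimulation and checkpoint ligands rose in 6 and fell in 2 of 14 members, with a median of 1.14 (percentile 96.7), but the median in the authors' deposited table was -0.30 (percentile 8.51), with 1 member called lower and none higher. Cd86, which costimulates T cells, rose from 9.22 to 33.5 ± 2.4 (SD, n = 3), but has an uncalled log2 fold change of 0.34 in the authors' deposited table. Cd274, which encodes the inhibitory ligand PD-L1, fell 5.32-fold, from 41.0 to 7.71 ± 0.97 (SD, n = 3; log2 change -2.28 ± 0.19, SE, limma adjusted p = 0.0056), and is called lower in the authors' deposited table. Cd80 was listed at 0 at day 0 and at 2.29, 2.98 and 3.14 at day 1.

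NF-kappaB targets rose in 10 and fell in 2 of 19 members, or 11 and 3 adjusted over the list alone (percentile 75.6). Nfkbie, an inhibitor of the pathway, rose from 7.74 to 35.4 ± 4.8 (SD, n = 3), and Rel, one of its transcription factors, fell 4.14-fold to 4.84 ± 0.98 (SD, n = 3), a call that ended without day 1 replicate 1. Nfkbia, another inhibitor, fell from 294 to 91.8 ± 6.1 (SD, n = 3), and Tnfaip3, also an inhibitor, is the only member with a call in the authors' deposited table, with a log2 fold change of -2.12, but did not pass the limma test (limma adjusted p = 0.070). Interferon-stimulated genes rose in 8 and fell in 4 of 19 members, or 10 and 4 adjusted over the list alone (percentile 63.3). On the log2 fold changes of the authors' deposited table their median was -0.31 (percentile 1.49), with 1 member called lower and none higher. Ifit1 fell from 59.3 to 1.81 ± 0.71 (SD, n = 3) and Isg15 from 38.8 to 7.90 ± 0.52 (SD, n = 3), while Gbp2 rose from 1.85 to 8.86 ± 0.25 (SD, n = 3). The day 0 value of Gbp2 stands for about 1.01 fragments, and its log2 fold change of 0.13 in the authors' deposited table is not called.

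Several metabolic and stress lists rose in part in limma, but camera at the preset correlation called none of them (adjusted p of 0.18 to 0.68). The authors' deposited table calls no member of the cholesterol synthesis, glycolysis, unfolded protein response or cell cycle lists higher. It calls 1 unfolded protein response gene lower. Metallothionein and oxidative stress genes rose in 9 and fell in 1 of 14 members (percentile 97.2), among them Txnrd1, a thioredoxin reductase, from 4.10 to 27.2 ± 3.5 (SD, n = 3), which the authors' deposited table also calls, and Gclm, needed for glutathione synthesis, from 1.13 to 26.4 ± 2.6 (SD, n = 3). Cholesterol synthesis genes rose in 9 of 17 members and none fell (percentile 96.2), with Fdft1 going from 1.64, about 1.51 fragments, to 12.4 ± 1.5 (SD, n = 3), against an uncalled log2 fold change of 0.88 in the authors' deposited table. On the log2 fold changes of the authors' deposited table, both lists lay above all 10000 random lists, with medians of 0.91 and 0.72. Glycolysis genes rose in 8 of 16 members and none fell (percentile 70.9), and Aldoa went from 88.3 to 537 ± 24 (SD, n = 3). Lysosome genes rose in 9 and fell in 1 of 17 members (percentile 75.6). Of these, Gpnmb was listed at 0 at day 0 and at 3.96, 6.65 and 7.82 at day 1, and the authors' deposited table calls it higher. Unfolded protein response genes rose in 6 and fell in 1 of 16 members (percentile 33.9), and cell cycle genes rose in 9 and fell in 2 of 24 members (percentile 62.8). Among reference genes, 4 of 12 rose and 1 fell (percentile 48.5), and Actb stood at 3296 at day 0 and 2613 ± 473 (SD, n = 3) at day 1, which did not pass the test (limma adjusted p = 0.36).

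**Figure D3:**
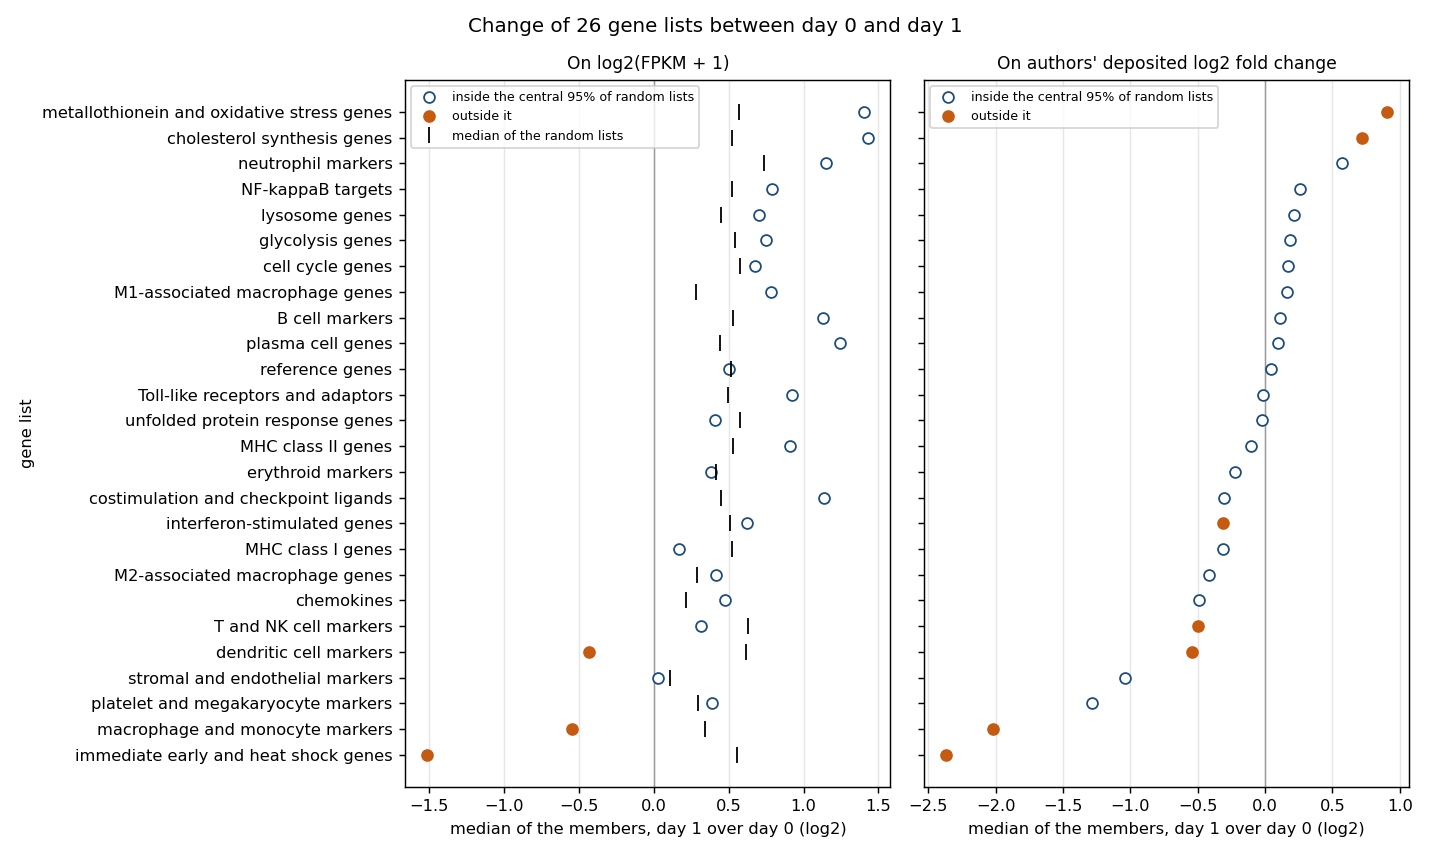
Median log2 change of the members of 26 gene lists (y axis), day 1 over day 0, on log2(FPKM + 1) at left and on the log2 fold changes of the authors' deposited table at right. Filled circles lie outside the central 95% of 10000 random lists matched on expression, and black ticks at left mark the median of those random lists. Immediate early and heat shock genes lie lowest in both panels, at -1.51 and -2.37.

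Across the 26 lists, 3 lay below the central 95% of random lists and none above it, and camera called 1 of the 25 lists with at least 3 tested members, or none with an estimated correlation. Over the lists' 361 tested entries, 150 rose and 66 fell, or 157 and 67 adjusted over the list alone, and 45 of the 150 rises were of genes listed at 0 at day 0.

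Genes that both tests called and that were above 0 in all 4 libraries were ranked by the authors' false discovery rate, a rule added after the values were seen. Id3, an inhibitor of helix-loop-helix transcription factors (chromosome 4, 136143497 to 136145755, GRCm38), rose 12.7-fold, from 26.1 to 331 ± 35 (SD, n = 3; log2 change 3.61 ± 0.17, SE, limma adjusted p = 0.0034). Apoe, a lipid carrier made by macrophages, rose 9.03-fold, from 126 to 1139 ± 53 (SD, n = 3; log2 change 3.16 ± 0.13, SE, limma adjusted p = 0.0032). Clcf1, a cytokine that acts on B cells, rose from 5.12 to 57.5 ± 10.0 (SD, n = 3). Tgfb3, a member of the transforming growth factor beta family, rose from 2.77 to 14.3 ± 0.7 (SD, n = 3). The day 0 values of Id3, Apoe, Clcf1 and Tgfb3 stand for about 10.2, 58.9, 4.3 and 2.0 fragments. Their log2 fold changes in the authors' deposited table are 2.94, 2.32, 2.17 and 3.13. The other 8 leading rises were Vamp1, Cacnb3, Slc2a6, Pde3b, D4Wsu53e, Alcam, Pde2a and Ccl22. In that order, their day 0 values stand for about 3.4, 1.5, 5.2, 1.4, 24.5, 6.9, 9.5 and 1.1 fragments. The 12 leading falls were Fos, Fosb, Klf4, Jun, Dusp1, Vcam1, C1qa, C1qc, Plk2, Atf3, Dusp6 and Ppp1r15a. Of these, Ppp1r15a, which helps restart translation after stress, went from 216 to 19.0 ± 6.0 (SD, n = 3), a call that ended without day 1 replicate 2.

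The 10 largest rises on the log2(FPKM + 1) scale were all of genes listed at 0 at day 0, and 4 of them carry the name of a ribosomal protein gene (Rps27, Rpl17, Rpl17-ps3 and Rps27a-ps2). Rps27, a ribosomal protein gene, was listed at 0 at day 0 and at 2412, 2021 and 1546 at day 1, whereas the log2 fold change in the authors' deposited table was 0.39 (false discovery rate 1). The 10 largest falls were of Mir5105 and AL807811.1, annotated as microRNA genes, of the pseudogenes Gm12563, Gm16245 and Rpl35a-ps2, and of Gm10281, Gm10181, Gm17604, Gm11027 and Gm10563. Mir5105 alone was listed at 1584400 at day 0 and at 1819, 435 and 285 at day 1. Whether these day 0 signals are reads of ribosomal RNA was not tested here.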

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

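The alternatives that use genes above 0, protein-coding genes, estimated fragments, calls shared with the authors or the authors' fold changes, and those for the agreement of libraries, were chosen after seeing the data. No paired analysis was possible because day 0 has 1 library. With limma, 7509 genes changed (4869 up, 2640 down). These totals stayed within 1.5 times, for both directions, with either pseudocount, either filter, a 2-fold minimum, both scalings and protein-coding genes alone, but the balance turned with the median log2 ratio set to 0 (3360 up, 3869 down). A threshold of 0.01 left 3483 (2318 up, 1165 down), by its construction. Leaving out 1 day 1 replicate gave 3634 to 5887 genes (2317 to 3875 up, 1317 to 2012 down), the lowest each time without replicate 2, with fewer samples in the fit. Without genes listed at 0 at day 0, 2834 rose and 2719 fell, so the excess of rises nearly ended. A gene at 0 can only rise, so this alternative takes away rises by its construction. With at least 10 estimated fragments at day 0, 2577 of far fewer tested genes changed (1093 up, 1484 down). The authors' table calls 492 (49 up, 443 down), and both tests share 466 (48 up, 418 down); the cause of this difference was not tested. Of 26 lists, 3 lay below the central 95% of random lists and 0 above. Lists above it numbered 3 with a pseudocount of 0.1, 1 with an equal upper quartile, 1 with the mean of the members, 0 to 2 with 1 replicate left out, 2 on the authors' fold changes and 3 over members above 0 at day 0. Lists below it numbered 5 on the authors' fold changes and 1 over members above 0 at day 0, and 2 to 3 with 1 replicate left out; the cause was not tested. The 1 list still below over members above 0 was that of immediate early and heat shock genes, which stayed below under every alternative run. The mean correlation of day 1 pairs was 0.941, and 0.879 with a pseudocount of 0.1, 0.964 with 5 and 0.955 without a filter. Of 141 named genes, 9 that rose in limma had a negative, uncalled log2 fold change in the authors' table: mt-Ta -0.43, Il10 -0.33, Il1b -1.32, Jchain -0.22, Camp -0.75, Il12a -0.30, Oas1a -0.83, Ccnb2 -0.25 and Hprt -0.32; the cause was not tested. A further 71 calls ended there, and 41 ended without replicate 2. At day 0 a 2 kb transcript needs an FPKM of 6.87 to reach 3 fragments, which limits every statement on low genes.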

Other observations

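All tests in this part were chosen after the results they concern had been seen.

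Further genes that both tests called higher were listed at 0 at day 0. Clec4e and Clec4d, neighbouring genes for pattern recognition receptors of myeloid cells, stood at 3.99, 3.58 and 4.29 and at 5.05, 4.91 and 5.67 FPKM in the 3 day 1 libraries. Pdcd1, which encodes the inhibitory receptor PD-1, stood at 5.01, 4.89 and 5.55, and Cdkn1a, a cell cycle inhibitor, at 10.5, 10.0 and 9.63. Crisp3 stood at 30.0, 38.0 and 41.0. Genes that both tests called lower included Cx3cr1, a chemokine receptor of monocytes and macrophages, at 32.8 against 0, 0.455 and 0.168, and Hes1, a target of Notch signalling, at 149 against 4.98, 5.88 and 6.90. These genes were chosen after their values were seen.

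The 2079 rises of genes listed at 0 at day 0 were weighed first. For 276 of them the day 1 level predicts 10 or more fragments at day 0 (median 15.9). Among all 5335 genes with such a level, 278 were listed at 0, where chance gives 0.0127, which argues against shallow sequencing alone. RNA truly absent at day 0 would give large folds, but 0.36% of them had a log2 fold change of 3 or more in the authors' table. Their median there was 0.63, so failed FPKM estimates at day 0 are a candidate explanation for this part. For the 1638 genes with fewer expected fragments (median 2.51), the median chance of seeing none is 8.12%, and shallow sequencing and failed estimates cannot be told apart, because each allows a 0 there. Their median log2 fold change in the authors' table was 0.45, so large rises were not typical of them there, and 376 of the 2079 genes had a negative one.

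Several pancreatic enzyme genes were higher at day 0. A list of 30 exocrine pancreas genes, none of them in the other lists, was written after 5 of them had been noticed, and 25 were measured. Of the 20 not noticed before, 95% had a negative log2 fold change in the authors' table against a median of 55% in 10000 sets of other genes of the same abundance (upper limit 75%). Their summed fragments at day 0 came to about 28.3 where the day 1 levels predict 13.9 (upper Poisson limit 22), but without Cela2a they came to 7.68 against 7.27. Chance in the FPKM values and a true difference therefore cannot be told apart, because 1 gene carries the excess, and 15 of the 25 genes were listed at 0 at day 0. Of the 25, limma called 7 lower and 2 higher, and the authors' table calls 5 lower (Amy2a2, Pnlip, Cel, Cpb1 and Klk1), which are the 5 noticed first. The most abundant were Amy2a2, at 72.1 against 20.2, 11.3 and 10.9, which both tests call, and Cela2a, at 54.7 against a mean of 17.7, which did not pass the limma test, while Prss2 was listed at 0 at day 0 and at 6.78, 7.13 and 3.13 at day 1. A trace of RNA from pancreas, which lies beside the spleen, may have been larger in the day 0 sample, although selection for MHC class II should remove such cells.

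The fall of macrophage markers was weighed last. A lower share of all macrophages and monocytes would lower every marker by one shared amount. With the counting error of day 0 included, the 17 tested markers deviated from a shared change by 100.5 in squared units of their SE, where 16 is expected. A lower share of macrophages and changes within them still cannot be told apart, because the spread of the lone day 0 library is not known and some of these markers are also made by other cells. The 17 markers together had about 122.6 fragments at day 0 where the day 1 levels predict 84.1 (upper Poisson limit 103), and 99.6 without Csf1r, the largest (limit 97). Both sums lie over their limits, the second by a narrow margin, with members that went both ways. Fragments of genes with several transcripts can be overstated here, so this margin does not settle whether counting chance plays a part for the list as a whole. The 3 C1q chains, picked after they were seen to fall, had about 18.5 fragments against 0.547. A loss of one macrophage subset, a change of state in culture and an effect of PSA all stay open and untested, and no cultured library without PSA was analysed here.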
